A study of Rattus norvegicus with 4 samples.

How the data were processed

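RNA-seq libraries of primary neonatal rat cardiomyocytes were compared, 1 library for each combination of medium (normal or high glucose) and time (24 h or 48 h), 4 in all. Per the labels' protocols, cells from Sprague-Dawley rats aged 1 to 2 days were plated in medium that held carnitine at 2 mM and both creatine and taurine at 5 mM, and strand-specific libraries were made from total RNA with a TruSeq Stranded Total RNA kit and sequenced on an Illumina HiSeq instrument. Samples were assigned to groups by their titles. The labels name no batch and no separate cultures behind a library.

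The submitters' processing notes name TopHat2 2.1.0, an aligner, Cufflinks, an assembler and quantifier, and the genome builds rn6 and Rnor_6.0, with no role or order. The counting tool, its use of strand and the annotation version are not given in the sources used here. The deposited tables hold lncRNA transcripts, each with an identifier and a position, and no protein-coding genes were analysed here. Raw read counts per transcript were deposited, per the file headers, for transcripts with at least 1 read. A transcript that a library's table did not list was taken as 0 there. FPKM values, read counts scaled by transcript length and library total, were deposited beside them, per the file headers. Transcript length in nt was deposited with the 24 h normal glucose library, and 1219 lengths of other transcripts were recovered from count and FPKM. Coordinates are 1-based positions in rn6 as the tables give them. No gene annotation of that build was used here, and none of the identifiers matched the reference gene table of another rat assembly, so no gene names, exons or introns are given. The tables give no strand, so whether the counts separate a transcript's reads from those of an antisense partner is not known. Reads shared with an overlapping protein-coding gene could not be separated here.

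Counts summed to between 846946 and 1075428 per library. Since the tables hold part of each library, the total behind the FPKM values was recovered as the value that gives count, length and FPKM together. Whether it counts reads, fragments or those assigned to genes is not given in the sources used here. It was 11877895 for normal glucose at 24 h, 15654067 for high glucose at 24 h, 14855771 for normal glucose at 48 h and 14225730 for high glucose at 48 h. Counts and FPKM with a deposited length fitted these totals within 1%, except for 2 transcripts in each 24 h library. CPM values were counts scaled by these totals. 1 read corresponded to between 0.0639 and 0.0842 CPM, and the floor of 3 counts to between 0.192 and 0.253 CPM. The median measured transcript had between 29 and 37 reads. Intervals of ratios are exact (Clopper-Pearson, conditional on the sum of both counts) at 95%, and those of shares are Wilson intervals. PCR reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only.

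Before the data were examined, the comparisons, the filter (a mean of at least 1 FPKM over the 4 libraries and a length of at least 200 nt), the pseudocount of 1, the 2-fold threshold, the gene lists, the rule for named transcripts and the alternatives were fixed. The filter was also to sum entries of the same gene and to leave out rows with no gene name. The tables name no genes, so neither step was done and transcripts were kept apart. Sums per locus (transcripts whose spans overlap by at least 1 base, in a chain) were added as an alternative. The rule named, for each time, the 10 measured transcripts with the highest and the 10 with the lowest log2 ratio of high over normal glucose. For both times, and for 48 h against 24 h over both media, it named the 10 highest and 10 lowest when transcripts with the same sign in both ratios were ranked by the smaller of the 2 sizes. Any transcript past the adjusted threshold could be named as well. Since identifiers are not paired with names, the 2 top-ranked in each direction are printed and the others are summarised. Ratios were taken on log2 (CPM + 1), which understates the change of low transcripts, and folds of named transcripts are ratios of CPM without the pseudocount. A fold against a library at 0 is a lower bound against 3 counts in that library.

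The planned test assumed FPKM values without counts (limma on log2 (FPKM + 1)), with edgeR's quasi-likelihood test if counts were found. Counts were found, so edgeR 4.0.16 (estimateDisp, glmQLFit, glmQLFTest) was run on the counts with the recovered totals as library sizes and terms for medium and time, which left 1 residual degree of freedom. Adjusted p-values are Benjamini-Hochberg over the measured transcripts, at a threshold of 0.05. No replicate libraries exist within a group here, so the spread comes from the disagreement between the times and media, and p-values rest on it. The common biological coefficient of variation of this fit was 0.367. The fit was tested on simulated data for high against normal glucose over both times, with 7321 transcripts of which 200 were changed. At a coefficient of 0.367 it recovered 58% of 4-fold and 99% of 32-fold changes with 6 false calls. At 0.1 it recovered 98% and 100%, also with 6 false calls. The simulation gave every transcript the same coefficient and placed changes only in transcripts above a minimum expected count. Transcripts that vary more between libraries than this coefficient were not simulated, so these percentages may not hold in the data.

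Agreement of ratios was given as Pearson's r and Spearman's rho across transcripts, with the overlap of 2-fold lists beside that of independent lists. The variation between libraries was split into medium, time and interaction contrasts. Groups of transcripts were compared with 10000 random lists matched on mean abundance in 20 bins. A transcript was called a single block where its length matched its span within 15 nt, and otherwise spliced. Windows of 1 Mb with at least 5 loci were compared with 1000 shuffles of loci. The contrast and list steps were also tested on simulated data.

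The alternatives fixed in advance were a pseudocount of 0.1, no filter on low values, a mean of at least 5 FPKM, median-of-ratios size factors, libraries rescaled to the same sum over measured transcripts, no term for the other factor, no abundance trend, leaving out each library in turn, and DESeq2 1.42.0. Alternatives added after seeing the data were TMM factors, limma 3.58.1 on log2 (FPKM + 1), sums per locus, the restriction to well-covered transcripts (mean count of at least 50) with and without those that switched, the lncRNA shares without the switching or the 10 most abundant transcripts, and, for the grouping of switching transcripts, a split of the libraries at the widest gap in log2 (CPM + 1) in place of a limit at the highest CPM divided by 8. Keeping RNAs under 200 nt, also fixed in advance, was not run, since it would add 0 measured transcripts. The directions of the 20 most abundant transcripts and of the chromosome medians under other scalings were also added after seeing the data. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 and R 4.3.3 were used.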

Results

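Long non-coding RNA (lncRNA) transcripts were measured by strand-specific sequencing of total RNA from primary cardiomyocytes of Sprague-Dawley rats aged 1 to 2 days. High glucose is used on these cells as a model of oxidative stress and apoptosis. Cells were kept in medium with 33 mmol/l glucose (high glucose) or with 5 mmol/l glucose and 28 mmol/l mannitol, a sugar alcohol that equalises the osmolality (normal glucose), for 24 h or 48 h. Each of these 4 groups was represented by 1 library, so the differences between libraries at a single time have no replicate check and no p-value is given for them. The lncRNA counts summed to 846946 in the normal glucose library at 24 h, 1069067 in the high glucose library at 24 h, 1075428 in the normal glucose library at 48 h and 904979 in the high glucose library at 48 h. Between 16715 and 17210 lncRNA transcripts had at least 1 read in a library. 17934 transcripts were listed in at least 1 library and 15231 in all 4. The measured set, with a mean of at least 1 FPKM, held 7321 transcripts with a median length of 775 nt. Of these, 6986 carried NONCODE identifiers, 109 Ensembl identifiers and 226 identifiers of assembled transcripts. The files pair the identifiers with no gene names, so transcripts are given by identifier and by position in the rat genome build rn6.

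Of the totals recovered from the FPKM values, whose unit (reads, fragments, or those assigned to genes) is not given in the sources used here, lncRNA transcripts took 7.13% (95% Wilson interval 7.12 to 7.15) in normal glucose and 6.83% (6.82 to 6.84) in high glucose at 24 h. At 48 h the shares were 7.24% (7.23 to 7.25) in normal glucose and 6.36% (6.35 to 6.37) in high glucose. The share in high glucose was therefore 0.958 times that in normal glucose at 24 h (95% counting interval 0.955 to 0.961) and 0.879 times at 48 h (0.876 to 0.881). The 10 most abundant lncRNA transcripts took between 7.97% and 8.88% of the lncRNA counts of a library.

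The first comparison asked which lncRNA transcripts differed between high and normal glucose after 24 h. NONRATT008254.2 (chromosome 13, 52667957 to 52671441, spliced, 1339 nt) was not listed in the normal glucose library and stood at 40.6 CPM in the high glucose library, at least 161-fold higher against a floor of 3 counts per library. NONRATT030593.2 (chromosome X, 71552333 to 71555281, spliced, 2886 nt) was 407-fold higher in high glucose (95% counting interval 72.8 to 16123.5), with 1 read in normal glucose and 537 in high glucose. NONRATT003063.2 (chromosome 1, 176940418 to 176942159, a single block of 1742 nt) was 174-fold lower in high glucose, with 88.7 CPM in normal and 0.511 CPM in high glucose (interval of the fold 87.8 to 403). NONRATT005600.2 (chromosome 10, 56527323 to 56531443, spliced, 733 nt) was 54.4-fold lower (37.4 to 82.3). The 48 h values of these transcripts differed. NONRATT003063.2 was again lower in high glucose at 48 h, 205-fold (104 to 475), and NONRATT005600.2 was 1.70-fold lower (1.59 to 1.83). NONRATT030593.2 was 117-fold lower there (49.8 to 361), the opposite direction. NONRATT008254.2 was 1.36-fold lower (1.20 to 1.54), with 601 reads in normal and 423 in high glucose. Whether these spans lie in introns, exons or untranslated regions of protein-coding genes was not analysed here. NONRATT008254.2 shared its locus with 7 other listed transcripts, NONRATT030593.2 with 3 and NONRATT005600.2 with 2, and the counts alone do not separate the reads of overlapping transcripts.

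Over the 7321 measured transcripts at 24 h, 171 were at least 2-fold higher and 187 at least 2-fold lower in high glucose, on the scale of log2 (CPM + 1). Together these were 4.89% of the measured transcripts. Counting error alone gave a mean of 0.68 higher and 0.47 lower in 100 simulated draws. All 358 ratios had counting intervals that excluded 1, which the 2-fold threshold with the pseudocount makes near certain at these library totals. 25 transcripts were at least 8-fold higher and 31 at least 8-fold lower. Spliced transcripts made up 114 of those 2-fold higher and 121 of those 2-fold lower, and single-block transcripts 57 and 66. The median log2 ratio was -0.04 (SD over transcripts 0.57), and 55.4% of the transcripts lay below 0. The balance of directions turned with median-of-ratios size factors, to 189 higher and 167 lower, a median of 0.05 and 42.6% below 0. It was near even with TMM factors (175 and 179) and with libraries rescaled to the same sum (179 and 178). Of the 10 transcripts ranked highest at 24 h, 2 were also at least 2-fold higher at 48 h, 3 were at least 2-fold lower there and 5 lay within 2-fold. Of the 10 ranked lowest, 3 were also at least 2-fold lower at 48 h, 2 were at least 2-fold higher and 5 lay within 2-fold.

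The second comparison asked the same after 48 h. NONRATT004374.2 (chromosome 10, 48880225 to 48881896, spliced, 718 nt) stood at 269.7 CPM, from 4006 reads, in normal glucose and was not listed in high glucose, at least 1279-fold lower. NONRATT005474.2 (chromosome 10, 45563313 to 45579139, spliced, 1014 nt, with 3 other listed transcripts at its locus) stood at 132 CPM in normal glucose and was not listed in high glucose, at least 628-fold lower. NONRATT021040.2 (chromosome 4, 180132182 to 180135931, a single block of 3750 nt) was 112-fold higher in high glucose (95% counting interval 60.6 to 234), and NONRATT000490.2 (chromosome 1, 82230930 to 82234051, a single block of 3122 nt) was 476-fold higher (85.0 to 18849.5), with 1 read in normal glucose. The 24 h values of these transcripts differed. NONRATT004374.2 was already at least 123-fold lower in high glucose at 24 h and NONRATT021040.2 was 2.76-fold higher (1.39 to 5.96), whereas NONRATT005474.2 was 1.80-fold higher (1.66 to 1.96) and NONRATT000490.2 was 92.3-fold lower (44.4 to 231).

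At 48 h, 209 transcripts were at least 2-fold higher and 316 at least 2-fold lower in high glucose, 7.17% of the measured transcripts. Counting error alone gave a mean of 0.31 and 0.21. All 525 counting intervals excluded 1, which is again near certain with this threshold and pseudocount. 26 transcripts were at least 8-fold higher and 43 at least 8-fold lower. The median log2 ratio was -0.14 (SD 0.67) and 63.6% of the transcripts lay below 0. Against 24 h in the same medium, the high glucose library at 48 h also had 506 transcripts beyond 2-fold, 188 higher and 318 lower. The comparisons without that library had fewer, 358 for glucose at 24 h and 342 for time in normal glucose. The larger count at 48 h and its lean to lower therefore cannot be told apart from a difference of that single library. The balance of directions depended on the scaling. With the library totals 39.8% of the 525 were higher. This part was 51.0% (256 higher, 246 lower) with TMM factors and 50.5% (252 and 247) with libraries rescaled to the same sum. The same sum makes the measured lncRNA totals equal by construction. With size factors a smaller lean to lower remained, at 47.2% higher (236 and 264) and a median of -0.05. TMM factors and the same sum moved the median log2 ratio from -0.14 to -0.01 and -0.02, so directions at 48 h are relative to that shift. Of the 10 transcripts ranked highest at 48 h, 2 were also at least 2-fold higher at 24 h and 3 were at least 2-fold lower there. Of the 10 ranked lowest, 2 were also at least 2-fold lower at 24 h and 1 was at least 2-fold higher.

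**Figure D1:**
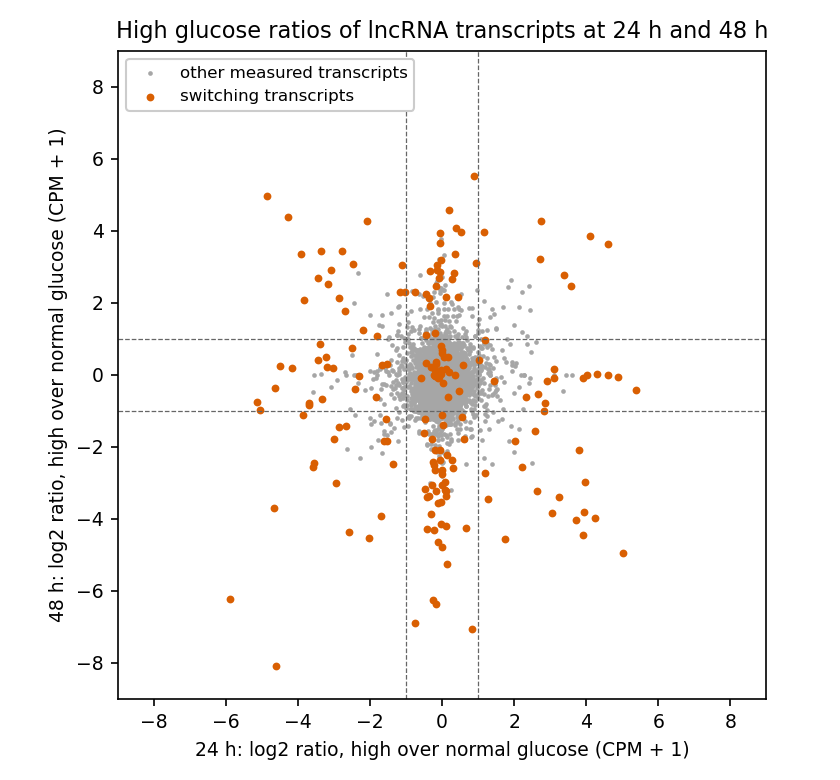
Log2 ratio of high over normal glucose, on CPM + 1, for each of the 7321 measured lncRNA transcripts at 24 h (x axis) and at 48 h (y axis). Orange points are the 185 transcripts with a mean count of at least 50 and an over 8-fold range between the 4 libraries, grey points are all others, and dashed lines mark 2-fold; 68 transcripts lie beyond 2-fold in the same direction at both times (28 higher, 40 lower) and 68 in opposite directions.

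Across both times, 1 lncRNA transcript passed the test, NONRATT003063.2, lower in high glucose, and its adjusted p was under 0.05 in 5 of 13 alternatives. It had 1054 and 1710 reads in normal glucose at 24 h and 48 h and 8 reads in each high glucose library, 174-fold lower at 24 h (95% counting interval 87.8 to 403) and 205-fold lower at 48 h (104 to 475). Its fitted log2 change was -7.54, with an adjusted p of 0.0252 in edgeR's quasi-likelihood test with a term for time (Benjamini-Hochberg adjustment over the 7321 measured transcripts), and it was lower in 2 of 2 pairs of libraries. It overlapped no other listed transcript. No transcript passed the adjusted threshold of 0.05 as higher. At an unadjusted p under 0.05, 127 transcripts were higher and 221 lower. These 348 are 4.75% of the tests, fewer than the 366 of evenly spread p-values, and their balance depended on the scaling, with 186 and 147 under size factors, 166 and 154 under TMM factors, and 161 and 151 with libraries rescaled to the same sum. Without the high glucose library at 24 h, in a fit with no term for time, they were 239 and 747, against 107 and 232 in that fit with all 4 libraries. With 1 library per group the times stood in for replicates, so a response that differed between 24 h and 48 h counted as spread in this test.

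Transcripts with large ratios in the same direction at both times did not pass, apart from NONRATT003063.2. NONRATT007078.2 (chromosome 11, 71547851 to 71550895, a single block of 3045 nt) was 20.3-fold higher in high glucose at 24 h (15.6 to 26.8) and 17.6-fold higher at 48 h (13.7 to 22.9), with an adjusted p of 0.0642 by edgeR. NONRATT009135.2 (chromosome 13, 111574581 to 111576875, a single block of 2295 nt) was 302-fold higher at 24 h (53.9 to 11958) and 97.6-fold higher at 48 h (26.7 to 812), with an adjusted p of 0.191. NONRATT004374.2 had 280 and 4006 reads in normal glucose and none in either high glucose library, with an adjusted p of 0.0767. Among the 10 transcripts ranked highest at both times the smaller of the 2 log2 ratios ran from 1.88 to 3.86, and among the 10 ranked lowest its size ran from 2.02 to 5.89. 8 of these 10 highest and 7 of the 10 lowest overlapped no other listed transcript. The count of calls depended on the tool and the filter. DESeq2 called 11 transcripts higher and 12 lower, 18 of them among these 20, and edgeR without the filter on low values called 21 and 24. Of these 45 calls without the filter, 42 were of measured transcripts and 0 had a mean count under 5. The call of NONRATT003063.2 was lost (0 calls) with TMM factors, with libraries rescaled to the same sum, without the abundance trend, by limma on log2 (FPKM + 1), and when any of the 4 libraries was left out. Its fitted log2 change was similar in these edgeR fits, at -7.41 with TMM factors and with the same sum, -7.54 without the trend, and -7.35 to -7.72 with a library left out. Its adjusted p ran from 1.67e-44 (DESeq2) to 0.483 over the 13 alternatives.

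**Figure D2:**
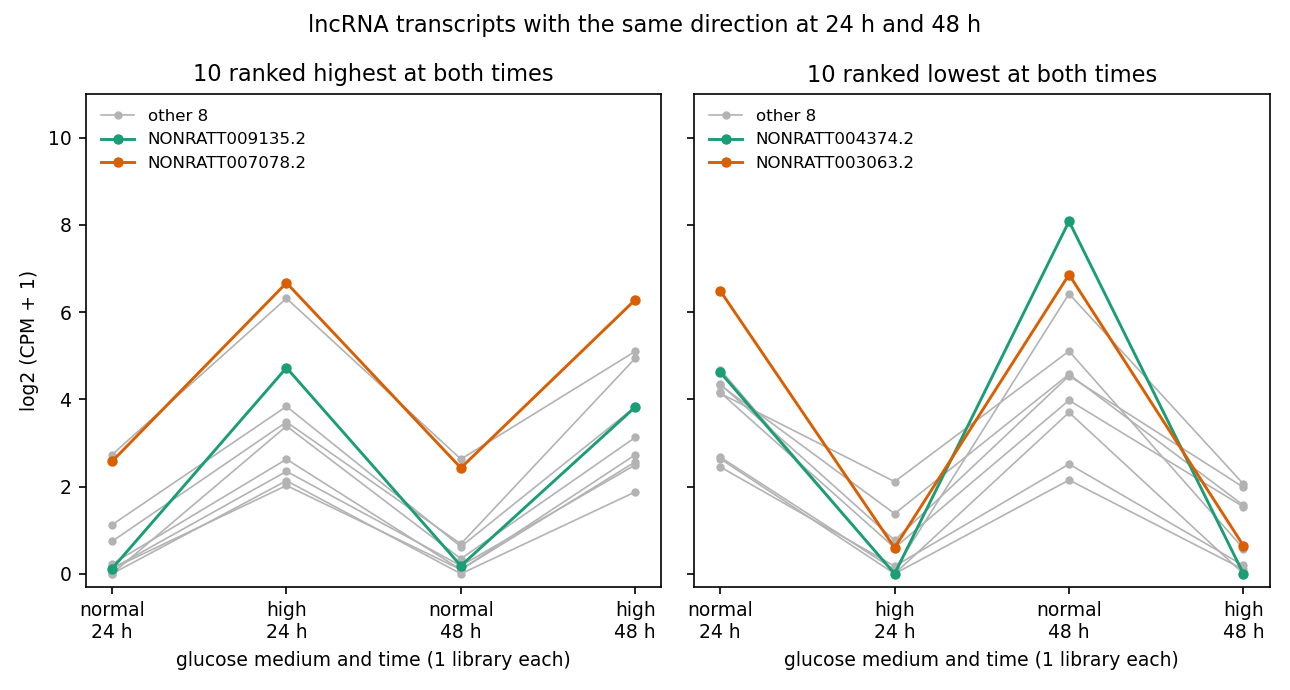
Level, as log2 (CPM + 1), of the 10 lncRNA transcripts ranked highest (left) and the 10 ranked lowest (right) in high glucose at both times, with 1 point per library and lines joining the 4 libraries of a transcript. The 2 top-ranked transcripts of each side are coloured; NONRATT007078.2 was 20.3-fold and 17.6-fold higher in high glucose and NONRATT003063.2 was 174-fold and 205-fold lower. The transcripts were chosen by these ratios.

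The comparison of 48 h with 24 h in both media gave no transcript past the adjusted threshold in the same edgeR fit. NONRATT024745.2 (chromosome 6, 963902 to 988572, spliced, 1368 nt) had 1 read in each 24 h library and 515 and 505 reads in normal and high glucose at 48 h, 412-fold higher in normal glucose (95% counting interval 73.6 to 16295) and 556-fold higher in high glucose (99.3 to 21992). NONRATT024883.2 (chromosome 6, 27565694 to 27582980, spliced, 683 nt) was not listed at 24 h and was at least 127-fold higher at 48 h in normal glucose and at least 259-fold higher in high glucose. NONRATT021972.2 (chromosome 4, 179482558 to 179512484, spliced, 4545 nt) was 89.6-fold lower at 48 h in normal glucose (48.4 to 188) and 61.5-fold lower in high glucose (35.0 to 119.5). NONRATT008808.2 (chromosome 13, 69908813 to 69917207, spliced, 3017 nt) was 638-fold lower (114 to 25243) and 97.6-fold lower (47.1 to 244). The smallest adjusted p by edgeR was 0.0549, a value that NONRATT024745.2 and NONRATT021972.2 shared with 1 other transcript, while 117 transcripts were higher and 194 lower at an unadjusted p under 0.05. These 311 are 4.25% of the tests, again fewer than 366. They were 138 and 166 under size factors, 139 and 169 under TMM factors, and 120 and 169 with the same sum. Without the normal glucose library at 48 h, in a fit with no term for medium, they were 226 and 690, against 93 and 156 in that fit with all 4 libraries. Of 13 alternatives, the adjusted p was under 0.05 in 7 for NONRATT024745.2, 7 for NONRATT021972.2, 5 for NONRATT008808.2 and 3 for NONRATT024883.2. In normal glucose 148 transcripts were at least 2-fold higher and 194 at least 2-fold lower at 48 h, and in high glucose 188 and 318. DESeq2 called 14 transcripts higher and 22 lower with time and limma 4 and 8. Fits that left out a library also had no term for medium. With all 4 libraries, edgeR without that term called 5 and 6.

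Measured transcripts showed little agreement between their high glucose ratios at 24 h and at 48 h. Across transcripts, which are not independent replicates, Pearson's r was 0.017 and Spearman's rho 0.080, and 54.3% had the same sign. The transcripts at least 2-fold higher at both times numbered 28, against 4.88 for independent lists, and those at least 2-fold lower at both times 40, against 8.07. A further 68 transcripts were beyond 2-fold in opposite directions, against 12.7 for independent lists. No library entered both ratios. The 48 h over 24 h ratios in the 2 media had an r of 0.050 and a rho of 0.069, with 31 transcripts shared as higher (3.80 for independent lists), 44 as lower (8.43) and 59 in opposite directions (11.4).

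Many of the well-covered transcripts with large ratios were near absent from some libraries and abundant in others. Among the 2867 transcripts with a mean count of at least 50, a limit set after the data were seen, 185 (6.45%) had a highest CPM over 8 times the lowest. How these switching transcripts group depends on the rule that parts high from low libraries. Where a library counted as high with at least the highest CPM divided by 8, 99 were low in 1 library alone, 41 of them in the high glucose library at 48 h, 22 in the normal glucose library at 48 h, 21 in the high glucose library at 24 h and 15 in the normal glucose library at 24 h. A further 28 were high in 1 library alone, and 58 parted the libraries 2 against 2. Of these 58, 12 parted high from normal glucose, 23 parted 48 h from 24 h and 23 put the normal glucose library at 24 h with the high glucose library at 48 h. Parted at the widest gap in log2 (CPM + 1) instead, 76 were low in 1 library alone (36 in high glucose at 48 h, 17 in normal glucose at 48 h, 15 in high glucose at 24 h and 8 in normal glucose at 24 h), 41 were high in 1 alone, and of 68 that parted 2 against 2, 14 followed glucose, 31 time and 23 neither. 154 of the 185 had the same grouping by both rules. By ratio, 24 of the 185 were at least 2-fold apart between the media in the same direction at both times and 35 in opposite directions. NONRATT003063.2, NONRATT007078.2 and NONRATT009135.2 were among the 12. Over all 2867 well-covered transcripts the 2 high glucose ratios had a rho of 0.173 and an r of -0.0037. Over the 2682 without a switch they had a rho of 0.210 and an r of 0.129, and the 2 time ratios a rho of 0.163 and an r of 0.066. Below a mean count of 20 the rho of the high glucose ratios was 0.003.

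Glucose, time and their interaction took nearly equal parts of the variation between the 4 libraries. Over the 7321 measured transcripts the glucose contrast held 33.5% of the sum of squares of log2 (CPM + 1), the time contrast 34.9% and the interaction 31.6%. The spread between libraries enters all 3 contrasts, and so does an overall shift of the ratios, since the contrasts were not centred. With TMM factors the glucose contrast held 32.9%. Over all 2867 well-covered transcripts time held the largest part, 36.4%, with 32.1% for glucose and 31.5% for the interaction. Over the 2682 of them without a switch, a set chosen by its own variation between libraries, glucose held 38.6%, time 32.2% and the interaction 29.2%.

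**Figure D3:**
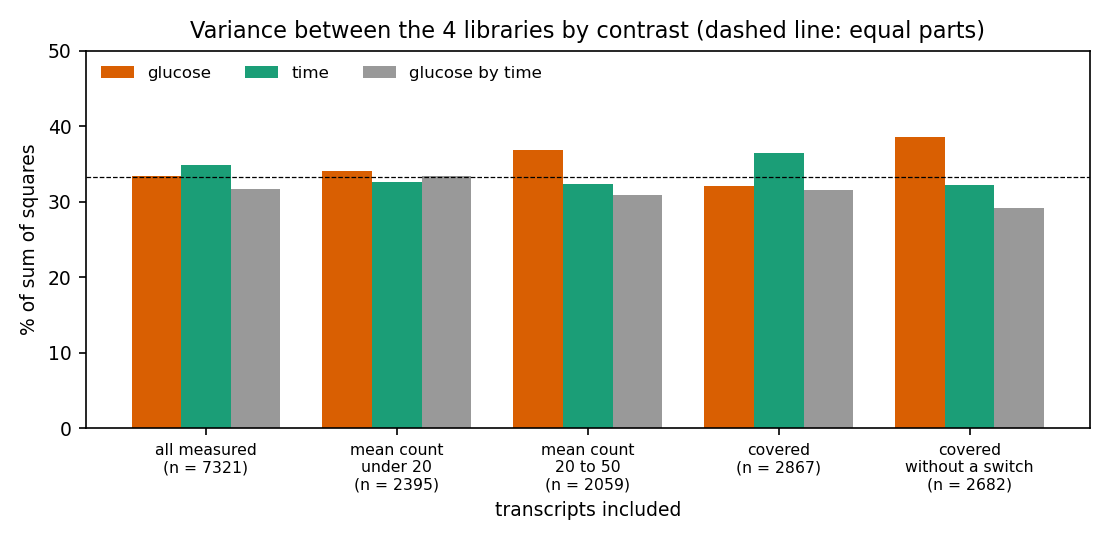
Percent of the sum of squares of log2 (CPM + 1) between the 4 libraries that falls on the glucose contrast, the time contrast and their interaction, for all measured lncRNA transcripts and for 4 sets by mean count. The dashed line marks equal parts; the 3 contrasts hold 33.5%, 34.9% and 31.6% over all measured transcripts 32.1%, 36.4% and 31.5% over covered transcripts (mean count of at least 50), and 38.6%, 32.2% and 29.2% over those without a switch.

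None of the 903 gene symbols in the 40 lists fixed for oxidative stress, apoptosis, glucose response, metabolism and cell type markers matched a transcript, since the identifiers carry no symbols. Groups by identifier, structure and chromosome were used in their place, chosen after the files were seen. At 48 h single-block transcripts had a median log2 ratio of -0.16, at percentile 0.175 among 10000 random lists of the same size matched on abundance, and spliced transcripts had -0.11, at percentile 99.975. At 24 h the medians were -0.04 and -0.03, at percentiles 36.5 and 64.02. The NONCODE, Ensembl and assembled transcripts had medians of -0.14, -0.09 and -0.13 at 48 h, at percentiles 18.96, 81.76 and 42.98. All 21 chromosomes had medians below 0 at 48 h, from -0.21 on chromosome 7 (453 transcripts, percentile 0.01) to -0.08 on chromosome 6 (313 transcripts, percentile 98.85). At 24 h chromosomes 7 and 6 were at percentiles 67.18 and 59.845. At 24 h the lowest median, -0.10, was that of chromosome X (260 transcripts, percentile 0.15), whose median at 48 h was -0.08 (percentile 95.555). The signs of chromosome medians depended on the scaling. With TMM factors 10 of the 21 lay below 0 at 48 h, and with the same sum 11. With size factors all 21 stayed below 0 at 48 h, from -0.128 to -0.004. The percentiles describe the pair of libraries at each time, and overlapping transcripts were drawn as if independent. Chromosomes 7, 6 and X were picked as extremes of the 21, which their percentiles do not allow for.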

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

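Of the tests in this part, those of the median gain at the same locus and of values missing from a list were set before their results were seen, and the others were chosen afterwards.

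For 4 of the top-ranked transcripts the high glucose ratio lay on opposite sides of 0 at 24 h and 48 h. The log2 ratio at 24 h minus that at 48 h was 5.81 for NONRATT008254.2, 9.99 for NONRATT030593.2, -9.82 for NONRATT000490.2 and 7.90 for NONRATT005474.2. With 1 library per group and time, these differences between the times were not tested. NONRATT008254.2 lacked reads in the normal glucose library at 24 h alone and NONRATT005474.2 in the high glucose library at 48 h alone. NONRATT030593.2 and NONRATT000490.2 parted the libraries crosswise, with normal glucose at 24 h and high glucose at 48 h together on one side.

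All 4 belong to the 185 well-covered switching transcripts, which range over 8-fold between the libraries. Counts drawn with the same read share in all libraries gave at most 0 such transcripts in 100 draws. The definition of the set, a mean count of at least 50 and an over 8-fold range, nearly fixes that result. It covers counting error only and leaves variation between separate libraries untested. A transcript missing from a library's list does not account for most, since 13.0% of the 299 low values (39) were absent. A response to high glucose of the same direction at both times does not account for most switches of 2 libraries against 2. Of these, 12 of 58 parted high from normal glucose (14 of 68 when libraries were parted at the widest gap). It could give others, since 24 of all 185 were at least 2-fold apart in the same direction at both times. But more, 35 of the 185, were at least 2-fold apart in opposite directions. Of the 99 low in 1 library alone, 41 were low in high glucose at 48 h and at most 22 in any other library (36 of 76 and at most 17 at the widest gap), and there a response at 48 h alone cannot be told apart from a difference of that single library. For the 67 that share a locus with other listed transcripts, those neighbours gained a median share of 0.010 of the lost CPM (interquartile range -0.013 to 0.326), which argues against reads passing to them as the general cause, but in 14 of 67 they gained at least 0.5 of it, against 5 that lost as much, so reassignment of reads between isoforms may account for part of those. Reads shared with overlapping protein-coding transcripts, differences between cultures and responses to glucose at a single time stay open.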

How the results depend on the processing

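TMM factors, limma, sums per locus, the restriction to well-covered transcripts and the shares without switching or abundant transcripts were chosen after seeing the data. The causes of the shifts below were not tested, except where fewer transcripts or a smaller pseudocount change a count by construction. Values count as moved here beyond 1.5 times for counts, 0.1 for median log2 ratios, 5 points for percents, 0.01 for the ratio of shares and the 95% interval of the main value for correlations. Of the values other than named transcripts, 61 moved and 116 did not. These 116 include the median log2 ratio at 24 h, which turned from -0.04 to 0.05 with size factors and 0.0050 with the same sum, and the 2-fold counts per locus at 24 h (118 and 134). The ratios of named transcripts kept their direction, but filters cannot change them.

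For high against normal glucose over both times (0 higher, 1 lower by edgeR), no filter on low values gave 21 and 24, DESeq2 gave 11 and 12, and sums per locus gave 1 higher. The call lower became 0 with TMM factors, the same sum, no abundance trend and limma, and 0 to 0 when each library was left out in turn. For 48 h against 24 h (0 and 0), no filter gave 29 and 42, size factors 2 and 1, no term for medium 5 and 6, DESeq2 14 and 22 (426 adjusted p-values were NA), limma 4 and 8, and sums per locus 1 and 1. Leaving out each library gave 0 to 22 higher and 0 to 37 lower. These fits left out the term for the other factor, and a lone library was assumed to vary like the others. Over the alternatives the adjusted p for NONRATT003063.2 ran from 1.67e-44 to 0.483, for NONRATT007078.2 from 1.92e-26 to 0.483 and for NONRATT004374.2 from 3.03e-06 to 0.913.

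The 2-fold counts (171 and 187 at 24 h, 209 and 316 at 48 h) became 326 and 389, and 405 and 826, with a pseudocount of 0.1. They became 48 and 62, and 76 and 130, at a mean of at least 5 FPKM. In well-covered transcripts they were 78 and 89, and 100 and 160, and without the switching ones 39 and 35, and 50 and 83. The median log2 ratio at 48 h moved from -0.139 to -0.0081 with TMM factors and -0.0159 with the same sum.

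Spearman's rho of the high glucose ratios (0.080) became 0.056 with the pseudocount of 0.1, 0.168 at 5 FPKM, 0.173 in well-covered transcripts and 0.210 without the switching ones. Their Pearson's r (0.017) became 0.083 with sums per locus and 0.129 in well-covered transcripts without a switch. For the time ratios r became 0.098 at 5 FPKM, 0.101 per locus and 0.076 in well-covered transcripts, and rho became 0.154 at 5 FPKM, 0.150 in well-covered transcripts and 0.163 without the switching ones. The glucose part of the variance moved from 33.5% to 38.6% in well-covered transcripts without a switch, and the ratio of lncRNA shares at 48 h from 0.879 to 0.894 without the switching transcripts.

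Libraries could not be paired by culture, because the groups share only the replicate number 1. The edgeR fit with a term for time does compare the media within each time. Keeping RNAs under 200 nt was not run, since it would add 0 measured transcripts, and the pseudocount does not enter the count tests. The median measured transcript had 29 to 37 reads per library. Below a mean count of 20 the rho of the high glucose ratios was 0.003, and whether depth sets it was not tested.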

Other observations

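The windows, the look at abundant transcripts and all tests in this part were added after the data were seen. The limits of the tests of lncRNA shares and of a shared trend were set before the results of those tests were seen, and that of the variance shares afterwards.

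Of the 20 lncRNA transcripts with the highest mean CPM, 9 were higher and 11 lower in high glucose at 24 h, with folds from 0.794 to 1.15, and 5 were higher and 15 lower at 48 h, with folds from 0.317 to 1.69. Both splits depend on the library totals. At 48 h the split was 10 and 10 with TMM factors and with libraries rescaled to the same sum, and 9 and 11 with size factors. At 24 h it turned to 11 and 9 with TMM factors and with the same sum, and to 12 and 8 with size factors. The lowest of these, NONRATT007996.2 (chromosome 12, 39957131 to 39959077, spliced, 217 nt), singled out after its values were seen, had 10114, 11784 and 12260 reads in normal glucose at 24 h, high glucose at 24 h and normal glucose at 48 h, but 3725 in high glucose at 48 h. Its fold at 48 h was 0.317 (95% counting interval 0.306 to 0.329), against 0.884 (0.861 to 0.908) at 24 h. The highest, NONRATT008253.2 (chromosome 13, 52667340 to 52680873), singled out in the same way, had a fold of 1.69 (1.64 to 1.74) at 48 h, from 7361 and 11933 reads, against 0.868 (0.840 to 0.898) at 24 h. The most abundant transcript, NONRATT008251.2 (chromosome 13, 52663050 to 52680902), which spans it, had folds of 1.00 (0.980 to 1.03) at 24 h and 0.807 (0.787 to 0.828) at 48 h. NONRATT008254.2, with no reads in normal glucose at 24 h, lies within its span. NONRATT008251.2 and NONRATT008253.2 each shared their locus with 7 other listed transcripts, and NONRATT007996.2 with 1. From normal to high glucose at 48 h NONRATT008253.2 went from 495 to 839 CPM and NONRATT008251.2 from 901 to 727 CPM. The counts alone do not separate reads of overlapping transcripts, and the intervals do not cover reassignment between them.

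Among 464 windows of 1 Mb with at least 5 loci, the lowest at both times lay on chromosome 13 from 84000001 to 85000000, where 5 of 6 loci were lower in high glucose at both times and the median log2 ratios were -0.70 at 24 h and -0.73 at 48 h. In 9 of 1000 shuffles of loci a window was as low. The highest window (chromosome 1, 142000001 to 143000000, 9 loci, medians 0.43 and 0.22) was matched in 140 of 1000 shuffles, and the correlation of window medians between the times (0.083) in 447 of 1000. Neighbouring loci can be parts of the same primary transcript, which shuffles ignore.

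In the 2682 well-covered transcripts without a switch, the high glucose ratios at 24 h and 48 h were related with a rho of 0.210. A trend with length, abundance or structure shared by both times was tested by adjusting both ratios for these properties, which left a rho of 0.208 and speaks against it. The glucose contrast held 38.6% of the variance there, against 32.2% for time and 29.2% for the interaction. But the glucose and interaction parts are built from the sum and the difference of the same high glucose ratios at 24 h and 48 h. Glucose exceeds the interaction wherever the products of these ratios have a positive sum, so the split is no separate test of their relation. The limit that each of the 3 contrasts is the largest in 1 of 3 cases by chance therefore does not apply. With the switching transcripts included time held more (36.4%, against 32.1% for glucose). The contrasts were not centred, so the overall shift of the ratios enters the glucose part. The split of this set was not run under another scaling. A relation of similar size was seen for time. In the same 2682 transcripts the 48 h over 24 h ratios in the 2 media had a rho of 0.163 and an r of 0.066. The high glucose ratios had an r of 0.129. An effect of high glucose on many lncRNA transcripts may account for the relation of the high glucose ratios. Differences between libraries unrelated to glucose cannot be told apart from it, since each group has 1 library.

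The lncRNA share of the recovered library total was lower in high glucose at both times, by 12.1% at 48 h. The 10 most abundant transcripts account for little of this. The ratio of the shares at 48 h was 0.883 without them, against 0.879 with them. The 10 most abundant of each library held 7.97% to 8.88% of its lncRNA counts, too small a part to give the whole fall. Without the switching transcripts the ratio was 0.894, so those do not account for most of it either. A true fall of lncRNA relative to other RNA, a difference in ribosomal RNA removal or RNA quality, and a difference in what the recovered totals count, were not tested and stay open.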
